A study of Homo sapiens with 8 samples.

How the data were processed

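RNA sequencing of 8 samples was analysed, 4 of NEUROD1 knockout and 4 of NEUROD1 control cells at day 27 of differentiation. Per the labels' protocols, MEL-1 human embryonic stem cells with a green fluorescent protein reporter in the insulin locus were differentiated into pancreatic endocrine cells, and reporter-positive cells were isolated by flow cytometry. Total RNA was then made into libraries with an Illumina TruSeq RNA kit and read on a HiSeq2000 in single 100-base reads. Each sample was placed in its group by its genotype label. Replicates are numbered in accession order, because the labels give no replicate numbers, so a number only names a sample. The labels give no batch, and nothing in them says whether replicates came from separate cultures, clones or differentiations, so the p-values measure only the spread between these samples, which may be technical.

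The deposited per-sample files hold 1 whole-number read count per gene symbol for 25559 symbols, not normalised. That these are raw counts was read from the values, which are whole and differ in total between samples, since the labels do not state it. The submitters' processing notes name bcl2fastq 1.8.4, TopHat2 2.1.0, Cufflinks 2.0.2 and DESeq without giving their roles. The only genome build in those notes is a mouse build, while the deposited gene symbols are human, so the build behind the counts is treated as unknown. The counting tool, its annotation and its use of strand are not given in the sources used here. Reads of overlapping or antisense genes may therefore be counted together, and counts of near-identical genes are uncertain. The authors' deposited table of their own comparison holds, per the file headers, a mean normalised count as signal, a log2 fold change with its standard error, a test statistic, and a p-value with its adjusted p-value for each gene. Its log2 fold changes are, from the values, control over knockout. The submitters' processing notes name DESeq, without a version, and the column names of the deposited signal and score values are those that DESeq2 writes.

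The total count per sample ran from 15319998 to 25418084. Genes passing edgeR's filterByExpr were tested, 15850 of 25559, which held 99.9% of the counts. Counts were scaled by the trimmed mean of M values (TMM) and fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, default settings, genotype as the only term), with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. Levels are CPM, counts scaled by TMM-adjusted library sizes. The floor of 3 counts was taken per library and covers counting error only, since reads without molecular identifiers are not independent molecules. Replicate pairs within a group differed well beyond sampling noise, with a chi-square per degree of freedom of 13.8 to 80.3 over genes with at least 40 summed counts, so no pair was treated as a library deposited more than once. Principal components were taken of log2 CPM with a pseudocount of 1. Chromosome medians were taken over genes averaging at least 5 CPM, with 1000 bootstrap draws.

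Gene lists were fixed before the data were examined: islet hormones, islet transcription factors, endocrine progenitor, beta cell maturity, alpha cell, and delta, epsilon and PP cell genes, proinsulin processing and granule cargo, exocytosis machinery, excitability and ion channels, glycolysis, respiratory chain nuclear subunits, Notch pathway, cell cycle and unfolded protein response. Lists for other cells that a culture or sort gate could hold covered neuronal, enterochromaffin, pancreatic progenitor, duct, acinar, liver and gut, pluripotency, mesenchyme, and endothelial and blood genes. Lists for RNA quality covered dissociation response, ribosomal protein, mitochondrially encoded and replication-dependent histone genes. Symbols were matched as written in the files or through older symbols. For each list the members past the threshold were counted, with adjustment over all genes and over the list alone. The 26 lists with at least 3 measured members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists.

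The genes named in the text followed a rule fixed before the data were examined: NEUROD1, the islet hormones, and the 12 largest rises and 12 largest falls among genes that passed the threshold, averaged at least 5 CPM and had all 4 knockout values above or below all 4 control values. From each list the rule also took up to 4 members, the 2 with the smallest adjusted p and the 2 most abundant of the rest. It took 122 genes, of which some are not reported here. A further 34 genes, and members listed beside small counts, were chosen after their values had been seen and are marked so where they stand.

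For a correction of transcript length and GC content, symbols were matched to GENCODE 29, which gave a value for 92.5% of tested genes. In each library log2 CPM deviations of genes above 5 CPM were fitted with natural splines of 5 degrees of freedom on length and GC content, and the fitted values served as offsets in edgeR. Since the build behind the counts is unknown, these lengths may differ from those of the authors' annotation. Coordinates are given only for NEUROD1, from GENCODE 29 on GRCh38.

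The tests were run first on simulated counts for the knockout and control comparison, drawn from the real means and library sizes with 200 genes changed. Of 15691 simulated genes tested, edgeR recovered 7 of 67 genes changed by 1.5-fold, 46 of 67 changed by 2-fold and 63 of 66 changed by 4-fold, and 7 of its calls, 5.69%, were unchanged genes. The fit with offsets and limma-voom gave the same counts. DESeq2 recovered 25 of 67, 53 of 67 and 65 of 66, with 25.5% of its calls false. In the simulated lists camera recovered the list raised by 1.5-fold and called 0 unchanged lists, of 20 lists simulated. Simulated genes were drawn independently of each other, while estimated correlations within real lists reached 0.947 (ribosomal protein genes). The simulation therefore does not show how often camera calls unchanged lists of correlated genes. With only 200 genes changed, its recovery of single genes does not carry over to a comparison with more changes.

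Alternatives fixed before the data were examined were other scalings (RLE size factors, library size, upper quartile), no filter or a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, edgeR with robust estimation, hormones left out of library sizes, each library left out in turn, a log2 fold change of at least 1, other list tests, and other thresholds on the authors' deposited table. Added after seeing the data were the offset for length and GC content, 1 surrogate variable from sva 3.50.0, and a fit without knockout replicate 3 and control replicate 2.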

Results

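RNA from 8 libraries of sorted insulin-reporter-positive cells was compared, 4 from NEUROD1 knockout and 4 from NEUROD1+/+ control cells. Both came from MEL-1, an established human embryonic stem cell line that carries green fluorescent protein in the insulin locus. The cells were differentiated in culture into pancreatic endocrine cells, sorted for the reporter and harvested at day 27. NEUROD1 is a basic helix-loop-helix transcription factor of endocrine and neuronal differentiation. The comparison asked how gene expression differs in insulin-reporter-positive cells that lack it. Total counts were 16896098, 15319998, 15532313 and 16430892 in knockout replicates 1 to 4 and 25418084, 17233890, 19183559 and 17253286 in control replicates 1 to 4. At this depth 3 reads of a gene corresponded to between 0.118 and 0.196 CPM, the unit of depth-scaled counts. Levels are means ± SD of normalised CPM and log2 fold changes are knockout over control ± SE, with n = 4 per group throughout. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 15850 genes unless another adjustment is named.

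The targeted gene was counted at similar levels in both groups. NEUROD1 stood at 516, 389, 316 and 487 CPM in knockout replicates 1 to 4 and at 467, 350, 462 and 351 CPM in control replicates 1 to 4. The means were 427 ± 91.6 and 408 ± 65.6 CPM, with a log2 fold change of 0.07 ± 0.18 and adjusted p = 0.781 by edgeR. Its sign turned without knockout replicate 1 (-0.05), without knockout replicate 4 (-0.02) and without control replicate 2 (-0.01). In the GENCODE 29 annotation of GRCh38, NEUROD1 lies on chromosome 2 from 181673088 to 181680876 on the minus strand. Its coding sequence, from 181677793 to 181678860, falls within an exon from 181676467 to 181678871. The labels do not give the position or kind of the edit, and reads counted over the whole gene do not show whether a transcript encodes protein, so this level neither goes against the labels nor checks them.

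Knockout cells contained less transcript of the islet hormones GCG and IAPP, and of many genes for hormone release. GCG, which encodes glucagon, was at 13358 ± 2545 CPM in knockout and 28981 ± 6200 in control cells. SLC30A8, the zinc transporter of insulin granules, fell from 1252 ± 168 to 131 ± 33.4 CPM, a log2 fold change of -3.25 ± 0.20. Against this, NEUROG3, the factor that starts the endocrine lineage, rose from 5.79 ± 1.94 to 29.1 ± 7.89 CPM, and SOX2, a factor of stem and foregut cells, from 4.03 ± 1.70 to 28.6 ± 1.58. SERPINA1, which encodes alpha-1 antitrypsin, rose from 509 ± 180 to 6135 ± 1753 CPM. Across the transcriptome 3118 genes were higher and 2710 lower in knockout cells by edgeR's quasi-likelihood test, of 15850 tested. With an absolute log2 fold change of at least 1 these counts were 1395 and 1224. In 35.1% of tested genes the 4 knockout values lay all above or all below the 4 control values, against 2.86% by chance. NEUROG3 was named after its values had been seen.

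**Figure D1:**
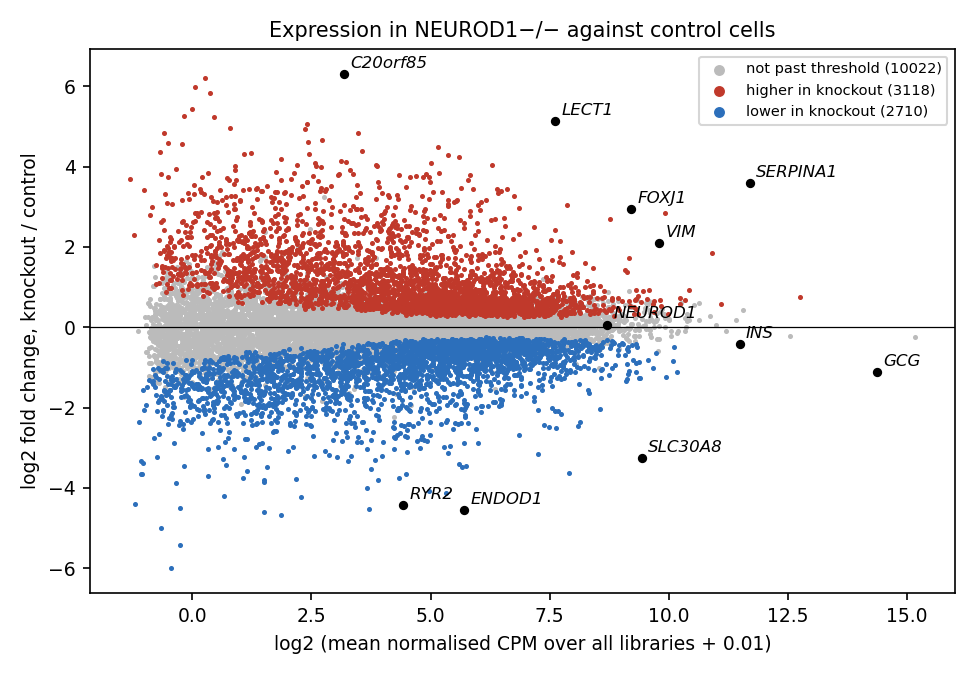
Log2 fold change (knockout over control, vertical axis) against log2 of mean normalised CPM plus 0.01 (horizontal axis) for the 15850 tested genes; coloured points passed an adjusted p of 0.05. The 3118 higher and 2710 lower genes lie at low and high expression alike.

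Of the 6 islet hormones, GCG and IAPP fell and the other 4 did not pass, while with the offset for transcript length and GC content, and with 1 surrogate variable, 4 of the 6 fell. Camera gave the list an adjusted p of 0.167 (adjusted p = 0.762 with an estimated correlation), and it passed only with the offset (adjusted p = 0.0314), against up to 0.360 over the other alternatives with the preset correlation. IAPP, the amyloid peptide released with insulin, dropped from 41.9 ± 11.7 to 7.65 ± 3.21 CPM (log2 fold change -2.46 ± 0.34, adjusted p = 4.4e-04). The log2 fold change of GCG was -1.12 ± 0.22 (adjusted p = 0.0031). INS averaged 2444 ± 1041 CPM in knockout and 3284 ± 773 in control cells, with a log2 fold change of -0.43 ± 0.30 and adjusted p = 0.294. For INS the call depended on the model: with the offset the value was -0.83 (adjusted p = 0.0052), and with 1 surrogate variable -0.65 (adjusted p = 0.0091). The mean GCG level was 8.83 times the mean INS level in control cells and 5.47 times in knockout cells. CPM are not scaled by transcript length and the reporter sits in the insulin locus, so neither ratio compares numbers of transcripts. SST, encoding somatostatin, had a log2 fold change of 0.42 ± 0.39 (adjusted p = 0.414), and knockout replicate 3 alone stood at 6941 CPM. Without that replicate it was -0.17. PPY, encoding pancreatic polypeptide, was at 229 ± 190 and 99.4 ± 69.2 CPM (adjusted p = 0.131), and passed without control replicate 2 (log2 fold change 1.76, adjusted p = 0.035) and without that and knockout replicate 3 (adjusted p = 0.0324). GHRL, encoding ghrelin, was at 3.73 ± 1.42 and 6.54 ± 2.15 CPM (adjusted p = 0.0646) and passed without knockout replicate 3 (log2 fold change -1.07, adjusted p = 0.0176), without that replicate and control replicate 2 (adjusted p = 0.0235), by DESeq2 (adjusted p = 0.0354), with library sizes alone (adjusted p = 0.0484), with the offset (log2 fold change -1.20, adjusted p = 0.0011) and with 1 surrogate variable (adjusted p = 0.00084). CHGA, the granule protein chromogranin A, was the most abundant of the named genes at 33763 ± 9099 and 40288 ± 5306 CPM (adjusted p = 0.396), and passed with 1 surrogate variable (adjusted p = 0.0333).

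**Figure D2:**
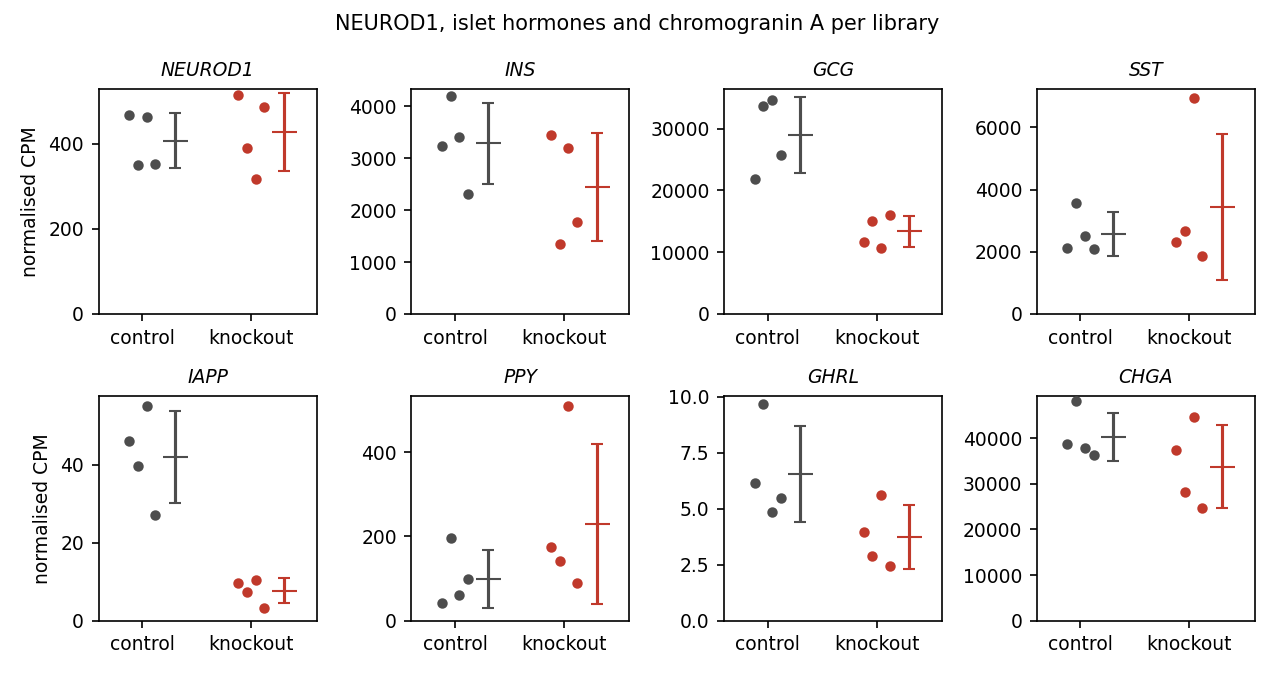
Normalised CPM per library (points) with group mean ± SD (bars), n = 4 per group, for NEUROD1, 6 islet hormones and CHGA in control and knockout cells. The 4 knockout values of GCG and of IAPP lie below all 4 control values, while NEUROD1, INS, SST, PPY, GHRL and CHGA overlap.

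Islet transcription factors moved down more often than up. Of 16 measured, 8 fell, 1 rose and 7 did not pass, and adjusted over the list alone 9 fell and 1 rose. RFX6, needed for islet cell formation, fell most in this list, from 474 ± 61.7 to 162 ± 32.3 CPM (log2 fold change -1.55 ± 0.17). MLXIPL, a glucose-responsive factor, changed by -1.05 ± 0.11, NKX6-1, a beta cell factor, by -1.02 ± 0.12, and ISL1, a LIM homeodomain factor, by -0.51 ± 0.11 on the log2 scale. MAFA, a factor of mature beta cells, fell from 5.75 ± 1.35 to 2.51 ± 0.987 CPM. GLIS3, the member that rose, changed by 0.70. PDX1, a master factor of pancreas and beta cells, was at 249 ± 27.0 and 309 ± 29.1 CPM (adjusted p = 0.0578). PDX1 passed without knockout replicate 3 (log2 fold change -0.37, adjusted p = 0.0357), without that replicate and control replicate 2, with library sizes alone, with upper quartile factors, by DESeq2, with the offset and with 1 surrogate variable (adjusted p between 0.0023 and 0.0487). As a list the factors were lower by camera (adjusted p = 0.0083), and with the offset for length and GC the call was lost (adjusted p = 0.072). It was also lost with the gene correlation estimated from the data (adjusted p = 0.283 with an estimated correlation). NKX6-1, ISL1, MAFA, PDX1 and GLIS3 were named after their values had been seen.

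The endocrine progenitor genes split. Of 19 measured, 4 rose, 7 fell and 8 did not pass, with the same counts adjusted over the list alone. The risers were NEUROG3 (log2 fold change 2.33 ± 0.27), SOX4 (1.22 ± 0.10), DLL1 (0.77) and AMOTL2 (1.16), while MYT1 (-1.34 ± 0.16) and ST18 (-1.06 ± 0.19), both zinc finger factors of endocrine differentiation, fell. Among 23 beta cell maturity genes, 9 fell, 4 rose and 10 did not pass. Adjusted over the list alone 9 fell and 6 rose. NPTX2, a neuronal pentraxin, fell from 464 ± 28.1 to 84.2 ± 29.5 CPM, and G6PC2, the islet glucose-6-phosphatase, from 31.2 ± 11.4 to 5.58 ± 3.83. GLP1R, the receptor for the incretin GLP-1, changed by -1.46 ± 0.25 on the log2 scale. The 4 that rose were ERO1LB, ADCYAP1 (log2 fold change 1.18), RBP4 (1.18) and SLC2A2. ERO1LB, an oxidase of proinsulin folding, stood at 1814 ± 450 against 948 ± 105 CPM. The glucose transporter SLC2A2 was at 3.39 ± 1.72 against 0.286 ± 0.0848 CPM, with only 22 reads over all control libraries. Neither list passed by camera (adjusted p = 0.428 and 0.142), while fry called the beta cell maturity list lower (adjusted p = 0.0026). Named after their values had been seen were NEUROG3, DLL1, AMOTL2, MYT1, ST18, G6PC2, GLP1R, ADCYAP1, RBP4 and SLC2A2.

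Markers of other islet endocrine cells did not move as groups by camera. Of 15 alpha cell genes, 4 fell (GCG, PLCE1, FAP and FEV), 4 rose (IRX1, TTR, GC and DPP4) and 7 did not pass, with the same counts adjusted over the list alone. PLCE1, a phospholipase, changed by -2.44 ± 0.18 on the log2 scale. Only 2 of the alpha cell genes rose without control replicate 3 or without control replicate 4. TTR, encoding transthyretin, was at 8684 ± 1291 CPM in knockout and 5185 ± 1505 in control cells (adjusted p = 0.0225). Its call was lost without knockout replicate 4 or control replicates 1, 3 or 4 (adjusted p between 0.0586 and 0.0687) and with the offset for length and GC (adjusted p = 0.302). FEV, a serotonergic factor, changed by -0.74 ± 0.25, and lost its call without knockout replicates 2 or 4 or control replicates 1, 2 or 3 (adjusted p between 0.0592 and 0.0996). Of 12 delta, epsilon and PP cell genes, 4 rose, BCHE, ANXA13, SPTSSB and AQP3, and 8 did not pass, also when adjusted over the list alone. ANXA13, an annexin, rose from 4.14 ± 4.45 to 78.2 ± 32.1 CPM. BCHE, encoding butyrylcholinesterase, changed by 0.96 ± 0.21, and with the offset by 0.53 (adjusted p = 0.0733). Camera passed neither the alpha cell list nor this list (adjusted p = 0.489 for each), while fry called this list higher (adjusted p = 0.0309). With the offset 3 of its genes rose and 2 fell. The genes IRX1, GC, DPP4, FAP, SPTSSB, AQP3 and FEV were named after their values had been seen.

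Many genes for granules, exocytosis and excitability were lower. Of 23 genes of the exocytosis machinery, 14 fell, 1 rose (SYT5, a synaptotagmin, by 1.06) and 8 did not pass. Adjusted over the list alone 14 fell and 3 rose, and 3 also rose by DESeq2 and without knockout replicate 4. SNAP25, a SNARE protein, fell from 292 ± 20.5 to 137 ± 13.8 CPM, and SYT7, a calcium sensor, from 1087 ± 111 to 540 ± 52.5. Of 20 genes for proinsulin processing and granule cargo, 9 fell, 1 rose (PAM, which amidates peptides, by 0.54) and 10 did not pass. Adjusted over the list alone 10 fell and 1 rose. SV2A, a synaptic vesicle glycoprotein, changed by -1.49 ± 0.11 and PTPRN, a granule membrane protein, by -1.26 ± 0.12 on the log2 scale. CPE, which trims prohormones, was at 2035 ± 245 and 1667 ± 204 CPM (adjusted p = 0.133). Of 24 excitability and ion channel genes, 10 fell and 14 did not pass, and 11 fell when adjusted over the list alone. RYR2, the ryanodine receptor of calcium stores, fell from 41.0 ± 11 to 1.88 ± 0.751 CPM (log2 fold change -4.44 ± 0.31). The channel subunit CACNA1C changed by -1.72 ± 0.19, the calcium pump ATP2A3 by -1.08 ± 0.18, and ABCC8, the sulfonylurea receptor, by -0.81 ± 0.13. Camera adjusted p-values were 7.7e-05 for exocytosis, 9.9e-05 for granule cargo and 9.9e-05 for excitability. The genes that fell numbered 17, 12 and 15 with 1 surrogate variable. With the offset for length and GC they numbered 16, 11 and 9, and 2 genes rose in each list. None of the 3 calls held with the correlation estimated (adjusted p = 0.0544, 0.283 and 0.283 with an estimated correlation). SYT5, PAM and PTPRN were named after their values had been seen.

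Neuronal genes also moved mainly down. Of 19 measured, 11 fell, 1 rose and 7 did not pass, and 12 fell and 1 rose adjusted over the list alone. ELAVL3, a neuronal RNA-binding protein, fell from 83.8 ± 7.54 to 22.3 ± 2.55 CPM. STMN2, a growth cone protein, was at 797 ± 196 and 974.8 ± 117 CPM (adjusted p = 0.215), and passed lower without knockout replicate 1 (adjusted p = 0.0316) and with the offset (adjusted p = 0.0035). Camera gave the list an adjusted p of 9.9e-05 (adjusted p = 0.0551 with an estimated correlation). Of 11 genes of enterochromaffin cells, the serotonin-producing cells of the gut, 7 fell, 1 rose (TRPA1, a cation channel, by 1.14) and 3 did not pass. Adjusted over the list alone 7 fell and 2 rose. LMX1A, a homeodomain factor, changed by -1.13 ± 0.13 and the adrenergic receptor ADRA2A by -1.79 ± 0.20. TPH1, which makes serotonin, was at 74.7 ± 55.7 against 300.2 ± 114 CPM (adjusted p = 0.0157). Camera called this list lower (adjusted p = 0.0171), but not without knockout replicate 3 (adjusted p = 0.0526) and not with the correlation estimated (adjusted p = 0.283 with an estimated correlation). TRPA1 and TPH1 were named after their values had been seen.

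**Figure D3:**
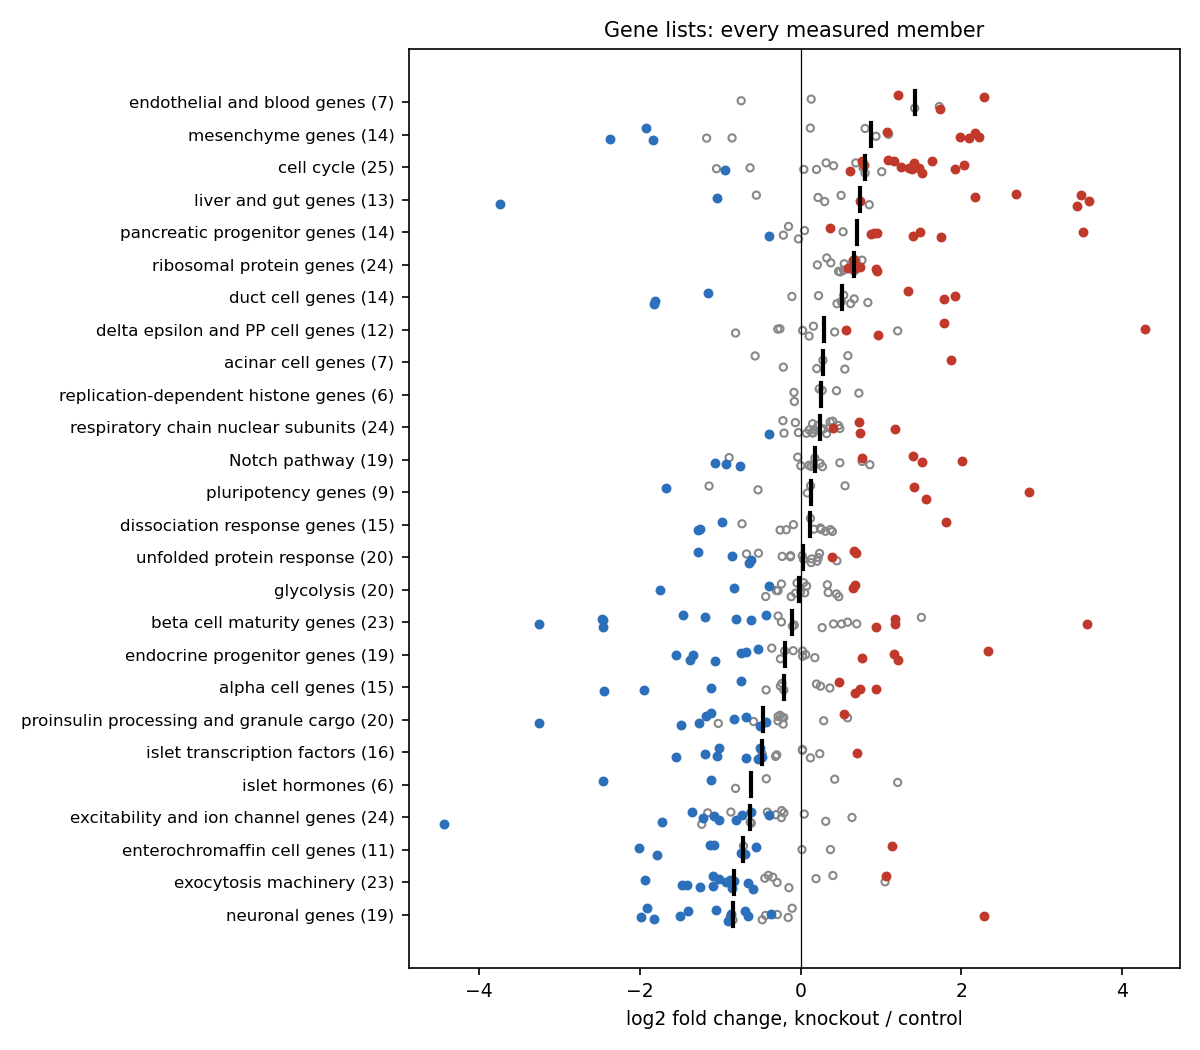
Log2 fold change (knockout over control, horizontal axis) of every measured member of each gene list (vertical axis); red and blue points were higher and lower past an adjusted p of 0.05, open grey points did not pass and black bars are list medians. Exocytosis, granule, excitability and neuronal genes lie mostly below 0, and cell cycle and ribosomal protein genes mostly above.

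Markers of pancreatic progenitors were more often higher. Of 14 measured, 8 rose, 1 fell (GATA4) and 5 did not pass, with the same counts adjusted over the list alone. TCF7L2, an effector of Wnt signalling, rose from 13.7 ± 2.19 to 25.9 ± 3.55 CPM and DCDC2, a doublecortin-domain protein, from 0.469 ± 0.266 to 5.42 ± 1.96. GATA4, a factor of foregut endoderm, changed by -0.39 ± 0.11, and its call was lost without knockout replicate 1 (adjusted p = 0.0517), without control replicate 4 (adjusted p = 0.0564) and with the offset (adjusted p = 0.226). Camera gave the list an adjusted p of 0.0556, and it passed without knockout replicates 1 or 4 or control replicate 4 (adjusted p = 0.0426, 0.0248 and 0.0486) and without a filter (adjusted p = 0.0210), but not with the correlation estimated (adjusted p = 0.310 with an estimated correlation). In the Notch pathway, 4 of 19 genes rose, 3 fell and 12 did not pass, also when adjusted over the list alone. The risers were the receptor NOTCH2 (log2 fold change 1.51 ± 0.38), the target genes HES1 (1.40 ± 0.34) and HEY2 (2.01 ± 0.45), and the ligand DLL1. DLL4 (-1.07 ± 0.13), MAML3 (-0.93 ± 0.13) and JAG2 (-0.75) fell, and camera did not pass the list (adjusted p = 0.946). DLL1, JAG2, NOTCH2, HES1 and HEY2 were named after their values had been seen.

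Cell cycle genes were more often higher in knockout cells, to an extent that depended on single libraries. Of 25 measured, 14 rose, 1 fell (CCND2, by -0.94) and 10 did not pass, and adjusted over the list alone 17 rose and 2 fell. CCNB1, the mitotic cyclin, rose from 14.1 ± 3.18 to 36.1 ± 12 CPM and CDK1, its kinase, from 3.23 ± 1.66 to 13.1 ± 7.81. MKI67, the proliferation antigen, was at 14.2 ± 8.36 and 12.3 ± 2.79 CPM (adjusted p = 0.706), and its log2 fold change of 0.20 turned to -0.21 without knockout replicate 3. The number that rose was 4 without control replicate 1 or 3, 7 without knockout replicate 3 or control replicate 4, and 9 without knockout replicate 2. The number that fell was 3 without knockout replicate 3 and 0 without any other single library. Camera called the list higher (adjusted p = 0.0356), but not without knockout replicate 3 (adjusted p = 0.311), knockout replicate 2 (adjusted p = 0.0598) or control replicates 1 or 3 (adjusted p = 0.0664 and 0.0616). It was not called with the correlation estimated (adjusted p = 0.807 with an estimated correlation), with the offset (adjusted p = 0.0908), without knockout replicate 3 and control replicate 2 (adjusted p = 0.0919) or with 1 surrogate variable (adjusted p = 0.192). CCND2, CDK1 and MKI67 were named after their values had been seen.

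Metabolic and stress lists did not pass by camera. In glycolysis 2 of 20 genes rose, 3 fell and 15 did not pass, also when adjusted over the list alone, and camera did not pass the list (adjusted p = 0.75). HK2, the inducible hexokinase, fell from 61.6 ± 21.1 to 18.3 ± 8.78 CPM and the neuronal enolase ENO2 from 408 ± 26.8 to 229 ± 41.5, while PFKM, a phosphofructokinase, changed by -0.39. PKM2, a pyruvate kinase, rose from 1004 ± 90.7 to 1601 ± 147 CPM. LDHA, lactate dehydrogenase A, had a log2 fold change of 0.65 ± 0.19 (adjusted p = 0.0254) and lost its call without knockout replicates 1 or 4 or control replicates 1, 3 or 4 (adjusted p between 0.0505 and 0.0805) and with the offset (adjusted p = 0.125). Without knockout replicate 3 or with 1 surrogate variable 6 glycolysis genes were lower, and with the offset 5. Without knockout replicates 1 or 4 or control replicates 1, 3 or 4 only 1 rose. Of 24 nuclear respiratory chain subunits, 4 rose (NDUFA4, NDUFB5, ATP5C1 and ATP5O), 1 fell (NDUFS1) and 19 did not pass, with 3 and 1 adjusted over the list alone. Only 2 rose without knockout replicate 1 or control replicates 1, 3 or 4, 6 rose without knockout replicate 2 or control replicate 2, 9 rose and 3 fell with 1 surrogate variable, and 2 rose and 7 fell with the offset. Camera did not pass them (adjusted p = 0.263). Of 20 genes of the unfolded protein response, 3 rose (XBP1, PDIA4 and CALR), 4 fell (ATF3, TRIB3, ASNS and EDEM1) and 13 did not pass (camera adjusted p = 0.827). Adjusted over the list alone 3 rose and 5 fell, and 2 fell without control replicate 1 or 3 but 6 without knockout replicate 3. With the offset 2 rose and 7 fell, and with 1 surrogate variable 5 rose and 8 fell. PDIA4, a disulphide isomerase, changed by 0.66 ± 0.14 and the stress factor ATF3 by -1.28 ± 0.28, and XBP1, a factor of this response, did not pass with the offset (adjusted p = 0.209). LDHA, HK2, PFKM, ATP5C1, ATP5O, NDUFS1, CALR, TRIB3, ASNS and EDEM1 were named after their values had been seen.

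Some liver and gut, duct and acinar genes were higher in knockout cells. Of all 15850 tested genes 3118 were higher, so a few risers in a list are not by themselves a shift of that list. Of 13 liver and gut genes, 6 rose, 2 fell (CDX2 and CDH17, both gut genes) and 5 did not pass, with 6 and 3 adjusted over the list alone. APOB, the apolipoprotein of lipid export, rose from 117 ± 27.0 to 752 ± 293 CPM and AFP, encoding alpha-fetoprotein, from 16.4 ± 5.91 to 178 ± 135. APOA1, encoding another apolipoprotein, was at 305 ± 95.3 against 446 ± 65.8 CPM (adjusted p = 0.0609), and passed lower without knockout replicate 1 (log2 fold change -0.79, adjusted p = 0.0071), with library sizes alone, by DESeq2, by limma-voom, with the offset and with 1 surrogate variable (adjusted p between 0.0085 and 0.0480). CDH17, a gut cadherin, was at 0.279 ± 0.157 against 3.90 ± 3.31 CPM, and 1 of these 2 fell without control replicate 1. Camera called the list higher (adjusted p = 0.0205), but not without control replicate 1 (adjusted p = 0.0895), by limma-voom (adjusted p = 0.056), with the offset (adjusted p = 0.0816), with 1 surrogate variable (adjusted p = 0.0756) or with the correlation estimated (adjusted p = 0.310 with an estimated correlation). Of 14 duct cell genes, 3 rose (ANXA2, ANXA4 and S100A11), 3 fell (KRT19, SPP1 and CLDN7) and 8 did not pass (camera adjusted p = 0.489), also when adjusted over the list alone. KRT19, a duct keratin, fell from 265 ± 49.4 to 119 ± 30.5 CPM and ANXA4 rose from 49.9 ± 1.81 to 126 ± 7.46. Without knockout replicate 1 or with 1 surrogate variable 5 duct genes rose, and with the offset 7 rose, while 3 fell each time. Among 7 acinar genes PRSS1, encoding trypsinogen, rose from 4.41 ± 0.664 to 16.1 ± 4.14 CPM and 6 did not pass, also when adjusted over the list alone (camera adjusted p = 0.446), while 2 rose without control replicate 2, with library sizes alone, by DESeq2, by limma-voom and with 1 surrogate variable. PRSS1 shares sequence with other trypsinogen genes, which leaves its count uncertain. AFP, CDX2, CDH17, ANXA2, S100A11 and CLDN7 were named after their values had been seen.

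Of 9 pluripotency genes, 3 rose (SOX2, ZFP42 and TERT), 1 fell (TDGF1, at 0.320 ± 0.158 against 1.02 ± 0.181 CPM) and 5 did not pass (camera adjusted p = 0.579). Adjusted over the list alone or with 1 surrogate variable 3 rose and 3 fell, and 2 fell by DESeq2 and without knockout replicates 1 or 2 or control replicate 2. LIN28A, the RNA-binding protein of stem cells, was at 13.6 ± 5.45 and 12.8 ± 0.763 CPM. Of 14 mesenchyme genes, 5 rose (COL6A3, VIM, PDGFRA, TWIST1 and ACTA2), 3 fell (COL5A1, THY1 and SNAI2) and 6 did not pass, also when adjusted over the list alone. VIM, the intermediate filament vimentin, rose from 338 ± 155 to 1439 ± 758 CPM and THY1, a surface glycoprotein, fell from 52.8 ± 6.70 to 10.2 ± 2.38. The list's median was 0.87 and its mean 0.31, while camera's direction was down (adjusted p = 0.962) and turned up with upper quartile factors. Only 3 genes rose without knockout replicate 2 or control replicate 1. Of 7 endothelial and blood genes, CLDN5, CD68 and LYZ rose and 4 did not pass, also when adjusted over the list alone, while 5 rose without control replicate 1 and by limma-voom. LYZ, encoding lysozyme, rose from 15.2 ± 5.76 to 73.6 ± 21.0 CPM. Camera gave this list an adjusted p of 0.0556, and it passed without knockout replicate 4 or control replicates 1 or 2 (adjusted p = 0.0254, 0.0021 and 0.019), without knockout replicate 3 and control replicate 2 (adjusted p = 0.0494), with library sizes alone (adjusted p = 0.0486) and with the filter at 1 CPM (adjusted p = 0.0409), but not with the correlation estimated (adjusted p = 0.310 with an estimated correlation). ZFP42, TERT, COL6A3, PDGFRA, ACTA2, COL5A1 and SNAI2 were named after their values had been seen.

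Lists that follow RNA quality and handling moved in part. Of 24 ribosomal protein genes, 7 rose and 17 did not pass, and 18 rose adjusted over the list alone. RPS6, a small subunit protein, was at 1011 ± 304 against 529 ± 120 CPM and RPL7, a large subunit protein with many processed copies and so an uncertain count, at 7.07 ± 0.797 against 3.65 ± 0.653, and neither passed with the offset (adjusted p = 0.0996 and 0.144). The number that rose was 2 without knockout replicate 1 or control replicates 1, 3 or 4, 4 without knockout replicate 3, 16 without control replicate 2 and 20 without knockout replicate 2. It was 12 with library sizes alone, 16 by DESeq2 and 22 with 1 surrogate variable, while with the offset 2 rose and 1 fell. Camera called this list higher (adjusted p = 0.0059), but not without knockout replicate 3 (adjusted p = 0.0526), with the offset (adjusted p = 0.158) or with the correlation estimated (adjusted p = 0.791 with an estimated correlation). Of 15 dissociation response genes, 1 rose (JUN, from 16.7 ± 3.10 to 58.4 ± 5.50 CPM), 3 fell (FOSB, ATF3 and NR4A1) and 11 did not pass, also when adjusted over the list alone. Its median was 0.12 and its mean -0.07, with camera's direction down (adjusted p = 0.946), and 5 fell without knockout replicate 3. With the offset 3 rose and 5 fell, with 1 surrogate variable 2 rose and 5 fell, and without control replicate 2, 2 rose. Of 6 measured replication-dependent histone genes 0 passed by edgeR, 2 had an unadjusted p under 0.05, and DESeq2 called 1 (camera adjusted p = 0.66). The calls went both ways between alternatives, with 3 lower with the offset, and 2 higher with 1 surrogate variable or without control replicate 2. The mitochondrially encoded genes were not analysed here. FOSB was named after its values had been seen.

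The genes with the largest falls and rises under the naming rule included several with known roles. ENDOD1, an endonuclease-domain protein, fell from 99.6 ± 14.6 to 4.24 ± 0.598 CPM (log2 fold change -4.56 ± 0.16, adjusted p = 1.2e-06 by edgeR). FAIM2, an inhibitor of apoptosis in neurons, fell by 4.54 on the log2 scale. The stress peptide UCN fell from 76.2 ± 45.9 to 4.32 ± 0.855 CPM and CRH, encoding corticotropin-releasing hormone, from 93.4 ± 16.6 to 8.31 ± 2.35. TDO2, a tryptophan dioxygenase, and FBN1, encoding fibrillin, fell by 4.07 and 3.64, and GPR142, a tryptophan-sensing receptor, by 4.01. RYR2, RASGRF1, TMEM130, ERMN and C8G completed the 12 falls, with log2 fold changes of -4.44, -3.82, -3.75, -3.64 and -3.53. Among the rises, LECT1, encoding chondromodulin, went from 11 ± 9.82 to 380.0 ± 119 CPM. C20orf85 and SNTN, both genes of ciliated cells, changed by 6.31 ± 0.53 and 4.49 ± 0.72, and AGR3, also expressed in ciliated cells, by 4.23 ± 0.74 on the log2 scale. ATP6V1B1, a proton pump subunit, changed by 5.06 ± 0.31, and GJB7, CYP4X1, KCNE1, LOC100506777, LOC100287718 and ANXA13 by between 4.28 and 4.83. GSTA3, a glutathione transferase whose near copies make its count uncertain, changed by 4.95. Controls held few reads of some of these genes, 17 in all for C20orf85 and 24 each for ATP6V1B1 and GSTA3.

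**Figure D4:**
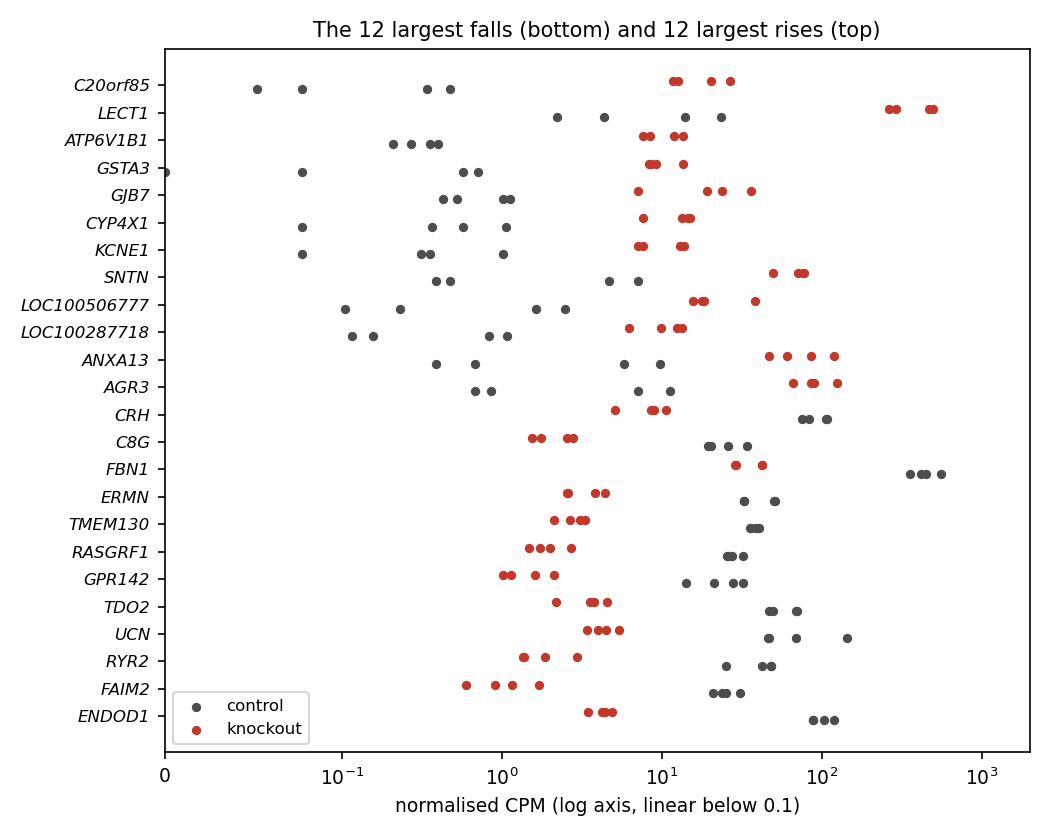
Normalised CPM per library (horizontal axis, logarithmic above 0.1 and linear below) of the 12 genes with the largest falls and the 12 with the largest rises; grey points are the 4 control and red points the 4 knockout libraries. For each gene the 4 knockout values lie apart from the 4 control values, from 4.24 against 99.6 CPM on average for ENDOD1 to 17.8 against 0.235 for C20orf85.

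Camera with the preset correlation called 9 of 26 lists in all and with the correlation estimated 0 of 26, of which 3 had an unadjusted p under 0.05. Fry, which asks whether a list's genes move on balance in a single direction and compares it with no other genes, called 12 lists.

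At an adjusted p of 0.05, the authors' deposited table called 3551 genes higher and 3270 lower in knockout cells. Of the calls made here, 3107 higher and 2691 lower genes were shared with the authors' deposited table, 99.5% of the total, and 0 had the opposite sign. These are different fits to the same counts. Across 15850 genes, which are not independent replicates, the fold changes here and in the authors' deposited table had a Pearson correlation of 0.998.

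Principal component 1 separated knockout from control libraries and held 67.5% of the variance of log2 CPM. Component 2, with 17.2%, placed knockout replicate 3 and control replicate 2 at its positive end and knockout replicates 2 and 4 at its negative end. Log2 fold changes fell with transcript length (Spearman correlation -0.34 across 11673 genes, which are not independent replicates) and, less so, with GC content (-0.12). Libraries of the same group also differed along length. Deviations of log2 CPM from the group mean correlated with length at -0.37, 0.63, -0.54 and 0.43 in knockout replicates 1 to 4. In control replicates 1 to 4 the values were 0.34, -0.67, 0.11 and 0.62. Knockout replicate 3 and control replicate 2 had the most negative value of their groups.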

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

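The tests of a whole-chromosome change, of duct cells and of liver-like cells were chosen only after the results they bear on had been seen, as were the offset for length and GC content and the surrogate variable.

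Of 314 groups of 4 values examined, 23 held a library far from the other 3, against 15.7 if values were independent and normally distributed. The groups share the same 8 libraries, and many of their genes were picked for their change. The number 15.7 is therefore not a chance expectation for these data. Of these 14 lay in knockout replicate 3 and 5 in control replicate 2, the pair at the positive end of principal component 2. In knockout replicate 3 the values apart from the others, in normalised CPM, were SST at 6941, ALDOA at 1724, SLC2A1 at 1130, ABCC8 at 379.9, KRT8 at 365, CDH2 at 111, MFNG at 94.7, LOC100506777 at 38.0, HK2 at 31.5, SPINK1 at 27.5, HIST1H1C at 21.3, CACNA1C at 17.1, THY1 at 13.8 and MAFA at 3.99. In control replicate 2 they were ALDOA at 1045, KRT19 at 339, RAB3A (named after its values had been seen) at 106, ATF3 at 18.4 and HIST1H1C at 11.03. ERO1LB in knockout replicate 2 was at 2483, SV2A in knockout replicate 4 at 67.0, NKX6-1 in control replicate 1 at 184 and APOB in control replicate 4 at 157. Without knockout replicate 3 and control replicate 2, 3390 genes were higher and 3227 lower in knockout.

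The count of genes that differed, 5828, was large for 4 against 4 libraries. Of the 35 splits of the 8 libraries into 4 and 4, only the real split, 1 of 35, called as many by edgeR. The highest of the others called 0, with at most 4441 genes at an unadjusted p under 0.05. Every other split mixed knockout with control libraries, so the difference between the groups added to its spread and made calls unlikely. The splits cannot exclude a chance difference between cultures, since the labels do not say whether replicates came from separate cultures. An offset for transcript length and GC content, which removed the trend of fold change with length, left 6995 calls, of which 4675 were among the original ones, which argues against that trend as the whole cause. The autosome whose median log2 fold change lay farthest from 0 was chromosome 6, at 0.14, against 0.58 for a gain of a chromosome in all cells, which argues against a whole-chromosome change in most cells. Genotype, clone and any unlabelled batch remain open, since the labels do not separate them.

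Some liver-type genes were higher in knockout cells. SERPINA1, APOB, AFP and ALB were picked because they rose, so their rise as a group is no test of liver genes in general. Each passed with the offset for length and GC content too, with a median log2 fold change of 3.03 over the 4, which argues against that trend as the cause for these 4. APOA1, APOA2, APOC3 and FGB did not pass in the main fit, with log2 fold changes of -0.55, 0.50, 0.22 and 0.85. By edgeR APOA2 passed higher without control replicate 2 (adjusted p = 0.0092) and without that and knockout replicate 3 (adjusted p = 0.0083). It also passed higher with 1 surrogate variable (adjusted p = 0.0441). ALB, APOA2 and FABP1 were named after their values had been seen. Liver-like cells admitted by the sort would bring their other abundant transcripts. Among ALB, APOA1, APOA2, APOC3 and FGB the largest rise was 81.7 CPM (APOA2), against 5626 CPM for SERPINA1. This set was chosen after the results had been seen. It leaves out APOB, TTR and FABP1, which rose by 635, 3498 and 2.81 CPM, and CPM are not scaled by transcript length. The set therefore cannot decide whether liver-like cells were the source of the SERPINA1 rise. For AFP, ALB and APOB too, with ALB at 27.8 CPM in knockout cells, a small share of such cells and a change within the sorted cells cannot be told apart. In the main edgeR fit and with the offset 0 of APOA1, APOA2, APOC3 and FGB passed higher, but APOA2 did in the other fits named above. The control levels of APOA1, APOA2 and APOC3 could also hide a small share. The APOA2 mean was 81.7 CPM higher in knockout cells, without passing in the main fit. Against 635 CPM for APOB this is not as small a part as against the SERPINA1 rise. ALB rose by only 25.3 CPM, and the FGB mean was 2.75 CPM higher without passing. TTR rose by 3498 CPM, a gene that islet cells also express. The sort for the insulin reporter should remove cells without it.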

How the results depend on the processing

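The offset for length and GC content, the surrogate variable and the fit without knockout replicate 3 and control replicate 2 were chosen after seeing the data. Over 3677 alternative values, 3001 planned and 477 added ones kept their direction and side of the threshold, and unless a reason is given the cause of a change was not tested. No paired analysis was possible because the labels give no replicate numbers.

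Genes higher in knockout numbered 2214 to 3219 and genes lower 1958 to 3074 when each library was left out, the lowest without control replicate 1, the deepest library. Requiring a log2 fold change of at least 1 left 1395 and 1224 by construction. With 1 surrogate variable 4436 were higher and 4104 lower. Lists called fell from 9 to 0 with the correlation estimated. The INS log2 fold change, -0.43, became -0.83 with the offset (adjusted p = 0.0052) and -0.65 with the surrogate variable (adjusted p = 0.0091), and was -0.66 to -0.23 over left-out libraries; over all alternatives its adjusted p ran from 0.0052 to 0.514, above the threshold in every planned one. That of NEUROD1 was -0.053 to 0.19 over left-out libraries and -0.14 with the offset.

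With the offset 13 genes passed with the opposite sign to the one they had passed with before. Among the lists, the 122 genes taken by the naming rule and the further 34, each value whose direction reversed had not passed before. Other list members and cilia genes named in the text were not followed for reversals. With each library left out, log2 fold changes ran from -0.048 to 0.22 for CDH2, -0.011 to 0.30 for HES6, -0.14 to 0.23 for LIN28A, -0.012 to 0.20 for LIN28B, -0.29 to 0.46 for MFNG, -0.21 to 0.44 for MKI67, -0.34 to 0.051 for SLC2A1 and -0.17 to 0.61 for SST. By limma-voom LIN28A was at -0.010. With the offset, ATP5B was at -0.23 (adjusted p = 0.030) and HIST1H2BD at -0.38 (adjusted p = 0.0078), both now past the threshold, HSP90B1 at -0.058, SPINK1 at -0.15 and SST at -0.23. With the surrogate variable MFNG was at -0.059. Without knockout replicate 3 and control replicate 2, HIST2H2BE was at 0.026, LIN28A at -0.12, MFNG at -0.18 and MKI67 at -0.24.

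For lists whose camera direction turned, the adjusted p-values were as follows. For mesenchyme genes they were 0.983 with upper quartile factors, 0.862 without a filter, 0.759 by limma-voom, 0.922 with the offset and 0.600 to 0.982 over left-out libraries. For dissociation response genes they were 0.922 with the offset and 0.431 to 0.982 over left-out libraries, for glycolysis 0.228 to 0.982, and for the Notch pathway 0.600 to 0.991, 0.909 with the surrogate variable and 0.912 without knockout replicate 3 and control replicate 2. With the offset, respiratory chain subunits and histone genes were each at 0.563. Depth limits genes near the floor of 0.118 to 0.196 CPM, and in simulation edgeR recovered 10.4% of genes changed by 1.5-fold. The simulation changed 200 genes, while 5828 were called in the data. Its adjusted threshold was therefore stricter, and this share does not carry over to the real comparison.

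Over all alternatives the adjusted p ran from 0.0324 to 0.466 for PPY, 0.00084 to 0.149 for GHRL, 0.0023 to 0.148 for PDX1, 0.0071 to 0.173 for APOA1, 0.00020 to 0.0733 for BCHE, 0.0034 to 0.302 for TTR, 0.00051 to 0.0996 for FEV, 0.0059 to 0.226 for GATA4, 0.0017 to 0.125 for LDHA and 0.00086 to 0.209 for XBP1. Among lists, over the alternatives with camera's preset correlation, it ran from 0.0030 to 0.0720 for islet transcription factors, 0.0022 to 0.311 for cell cycle, 0.0020 to 0.0895 for liver and gut, 0.0062 to 0.0526 for enterochromaffin cell, 0.021 to 0.147 for pancreatic progenitor and 0.0021 to 0.114 for endothelial and blood genes. With the correlation estimated these were 0.283, 0.807, 0.310, 0.283, 0.310 and 0.310.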

Other observations

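The list of motile cilia genes seen first, the test of duct cells and the offset for length and GC content were chosen only after the pattern had been seen; a further cilia list and a primary cilium list were written before their values were looked at.

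Genes of motile cilia were higher in knockout cells. FOXJ1, the master factor of motile ciliogenesis, was at 1042 ± 250 CPM in knockout and 136 ± 64.2 in control cells (n = 4 per group, adjusted p = 1.5e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and TPPP3, a tubulin-polymerising protein of cilia, at 1689 ± 403 and 237 ± 115. In a list of 29 such genes chosen because some had been seen to rise, 27 rose. In a list of motile cilia genes not looked at before, 50 of 51 measured members rose, with a median log2 fold change of 2.24 and of 2.13 to 2.46 when each library was left out. Examples were MORN5 (3.35 ± 0.32), WDR63 (3.02 ± 0.30), RSPH4A, a radial spoke protein (2.70 ± 0.23), and DNAAF1, a dynein assembly factor (2.04 ± 0.21). TEKT3, a tektin, did not pass (0.29 ± 0.34, adjusted p = 0.521). These genes were not silent in control cells, where 37 of the 51 averaged at least 5 CPM. Some cilia genes varied widely among control libraries. In control replicates 1 to 4 FOXJ1 was at 89.6, 216, 79.1 and 159 CPM, and SNTN at 0.386, 7.08, 0.470 and 4.70. Others varied little, such as NME5 of the list not looked at before, at 8.13 ± 0.541 CPM in control cells. The cause of this spread was not tested. Of 30 primary cilium genes, for the sensory cilium that most cells carry, 18 rose, 1 fell (CEP164, by -0.44) and 11 did not pass. Their median was 0.61, and IFT57, an intraflagellar transport protein, changed by 1.54 ± 0.10. Camera adjusted p-values over the 3 lists were 5.0e-48 for the list not looked at before and 3.5e-06 for the primary cilium list (adjusted p = 0.0206 and 0.109 with an estimated correlation).

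A trend with transcript length and GC content is argued against as the cause, since the median of the list not looked at before was 2.06 with the offset. A programme of motile cilia genes in knockout cells is a candidate explanation that stays open. In the list not looked at before 50 members rose, but so did 60.0% of primary cilium genes. The primary cilium list cannot decide the question, since many of its members, such as the intraflagellar transport genes, also serve motile cilia. Ciliated duct cells admitted by the sort also stay open: 3 of 14 duct genes rose (ANXA2, ANXA4 and S100A11) and 3 fell (KRT19, SPP1 and CLDN7), 7 rose and 3 fell with the offset, and the control level of KRT19, 265 CPM, could hide a small share. Gating on the insulin reporter should remove cells without it, and 12 of the 14 duct genes averaged at least 5 CPM in control cells too. Neither the number of ciliated cells nor the cilia themselves were measured here.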
